A study of Mus musculus with 8 samples.

How the data were processed

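RNA abundance was measured in epithelium taken from the incisors of mice on a mixed genetic background. Per the labels' protocols, whole incisors were treated with accumax, a mixture of enzymes that loosens tissue, the epithelium was separated mechanically from the mesenchyme, and total RNA was purified on columns. Each sample was labelled with Cy3 and hybridised alone to a 1-colour Agilent array. There were 8 arrays, 4 of wild type and 4 of Bmi1-null epithelium, grouped by the genotype given for each sample. For wild-type replicate 1 the number in the title differs from that in the name of its deposited scanner data, which were used as listed for that sample; the authors' column for the sample ranks the probes exactly as those data do. The labels do not say that the samples came from separate animals, so p-values here measure the spread between these samples.

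Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1 under protocol GE1-v5_95_Feb07, and the array design refers to genome build mm9. The deposited scanner files give for each spot a processed signal, which is an intensity on a linear scale after background subtraction and spatial detrending, with very low values replaced by a surrogate and no scaling between arrays. They also hold the median intensity of the spot and of its local background, per the file headers, and flags that mark spots well above background, saturated or outlying. The authors' deposited value table holds log2 values. Its source is not given in the sources used here. Set against the scanner files, each of its columns ranked the probes exactly as the median signal of the same array (Spearman correlation 1), with column medians of 6.76 to 6.77 and values from 4.48 to 17.54 over the columns. It was therefore read as quantile-normalised log2 median signal without background subtraction, a reading inferred from the values. It served as an alternative.

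Each array carried 41174 probes, with 1 spot each, after 1417 control spots were left out. The processed signal was put on the log2 scale and the array's 75th percentile was subtracted. A value of 0 is therefore the level of the array's 75th percentile. The 141 spots marked as outliers over all arrays were left out, and no probe was saturated. A probe was tested when it was well above background on at least 3 of the 8 arrays, counted without regard to genotype. The files name probes by accession only. Symbols came from a RefSeq table of assembly GRCm38.p6, which named 24844 probes (60.3%) and left 16330 without a symbol; no probe matched several. That table served for names and gene order only, and no coordinates are printed. Of several probes for a gene the one with the highest mean over the 8 arrays stood for it. In 5469 genes with more than 1 tested probe, 0 had probes that differed significantly in opposite directions. This gave 22435 genes, 14074 with a symbol and 8361 without.

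Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change is Bmi1-null minus wild type. The standard error (SE) is the moderated one. Values per genotype are mean ± SD. Where a probe was not well above background on any array of a genotype, only a bound was known there. The fold is then given as "at least", the brighter genotype's mean against the dim genotype's mean of, per array, the higher of the lowest well-above-background signal and the probe's own. The limma p given beside such a bound tests the full difference, signals below background included, and not the bound. Single values were compared with exact permutation tests, 2-sided, whose smallest p with 4 against 4 is 0.0286. Before the data were examined, 31 gene lists with 550 genes were fixed from textbook knowledge. Of these, 30 were tested with limma's camera at a preset correlation of 0.01 between genes. The list of sex-linked genes was used to read the sex of each sample. Camera used the 22374 genes with complete values.

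The genes named were also fixed beforehand: Bmi1, Cdkn2a and Cdkn2b; then in each direction up to 10 genes with a symbol, past the threshold and without overlap between genotypes, by size of change. Where fewer than 10 passed, genes of smallest p filled the places and are given as not passing. From each list came the members past the threshold, up to 4, or otherwise the 2 of smallest p. Any other gene is named as chosen after its values were seen. Some genes that this rule took are not reported here.

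The alternatives fixed beforehand were normexp background correction with an offset of 50, quantile or median scaling, the authors' table, no filter or a filter on all 8 arrays, the mean of a gene's probes, trended and robust variances, array weights, slide as a block, sex as a covariate, and each array left out in turn. For lists, camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in one direction, were run. Normexp used the median signal of spot and background, since the scanner files used here have no mean signal column; a mean signal had been planned. Raising dim values to a common floor and keeping the outlying spots were chosen after seeing the data.

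The precision of each comparison is limited by the number of arrays. On simulated arrays built from the means and spreads of the 22435 genes, in 5 simulations with 200 changed genes each, the test recovered 19.6% of genes changed by 1 on the log2 scale, 66.0% of those changed by 2, 94.4% of those changed by 4 and 99.6% of those changed by 6. There were 8.8 false calls per simulation on average. The simulated noise was independent between genes and had no floor for dim signals, and far more genes changed than the real comparison called. The adjusted threshold is easier to pass in that case, so these rates may overstate recovery in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.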

Results

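The data compared dental epithelium of mice homozygous for a null allele of Bmi1, a subunit of Polycomb repressive complex 1, with wild-type dental epithelium. The mouse incisor grows throughout life, and its epithelium holds progenitors as well as the ameloblasts that make enamel. There were 4 arrays of each genotype, all on 1-colour arrays. The 75th percentile of the processed signal was 1177 ± 538 (SD, n = 4) in wild type and 603 ± 182 (n = 4) in Bmi1-null (exact permutation p = 0.0857). Probes well above background made up 71.4% ± 2.10 (SD, n = 4) of the wild-type arrays and 66.4% ± 1.64 (n = 4) of the Bmi1-null arrays (exact permutation p = 0.0286, the smallest possible), so the Bmi1-null arrays were dimmer. Slide 1 and slide 2 each held 2 arrays of each genotype, scanned together. By Xist and Y-linked genes, 2 wild-type samples were male and 2 female, while 3 Bmi1-null samples were male and 1, replicate 1, was female. Bmi1-null replicate 1 stood apart on the main axis of a principal component analysis, which held 39.95% of the variance, with a score of 129.5 against −50.02 to 6.16 for the other arrays.

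Bmi1 itself was lower on every Bmi1-null array. Its brighter probe gave 1.22 ± 0.05 (SD, n = 4) in wild type, and −2.92, −1.22, −1.23 and −1.04 in Bmi1-null replicates 1 to 4. The log2 change was −2.82 (SE 0.39), a 7.07-fold lower level, with a limma adjusted p of 0.0631, above the threshold. The exact permutation p for this probe alone was 0.0286 (n = 4 and 4). A dimmer second probe had −1.73 ± 0.32 in wild type and −6.32 ± 1.75 in Bmi1-null (SD, n = 4 each). Where these probes lie relative to the targeted part of the gene is not given in the sources used here. The change passed in 7 of 21 alternatives: with normexp (adjusted p = 0.0147), median scaling (0.0387), the authors' table (0.0467), trended variances (0.0253), array weights (0.00295) and sex as a covariate (0.0377), and without Bmi1-null replicate 1 (log2 change −2.38, adjusted p = 0.00114). Over all alternatives the adjusted p ran from 0.00114 to 0.246. Within the slides the change was −3.27 and −2.37.

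Cdkn2a, which encodes the cell cycle inhibitor p16Ink4a and the p53 regulator p19Arf and is a classical target of Bmi1, was higher on all 4 Bmi1-null arrays. It was not well above background on any wild-type array and was so on all 4 Bmi1-null arrays, a rise of at least 11.3-fold (limma adjusted p = 0.00614). Its neighbour Cdkn2b, which encodes p15Ink4b, measured −0.27 ± 0.98 (SD, n = 4) in wild type and 1.84 ± 0.87 (n = 4) in Bmi1-null. Its log2 change of 2.11 (SE 0.56) did not pass (adjusted p = 0.689; exact permutation p = 0.0571). Of the 7 inhibitors of cyclin-dependent kinases listed, 1 rose and 0 fell, or 2 and 0 adjusted over the list alone. The median log2 change of the list was 0.56 (camera adjusted p = 5.98e-04; adjusted p = 0.164 with an estimated correlation), and 1.0 and 0.26 within the slides. The list did not pass with normexp (adjusted p = 0.164). Cdkn2a kept its direction but not its call with normexp (log2 change 1.97, adjusted p = 0.249), in the authors' table (2.08, adjusted p = 0.433) and with a common floor for dim probes (2.58, adjusted p = 0.687).

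**Figure D1:**
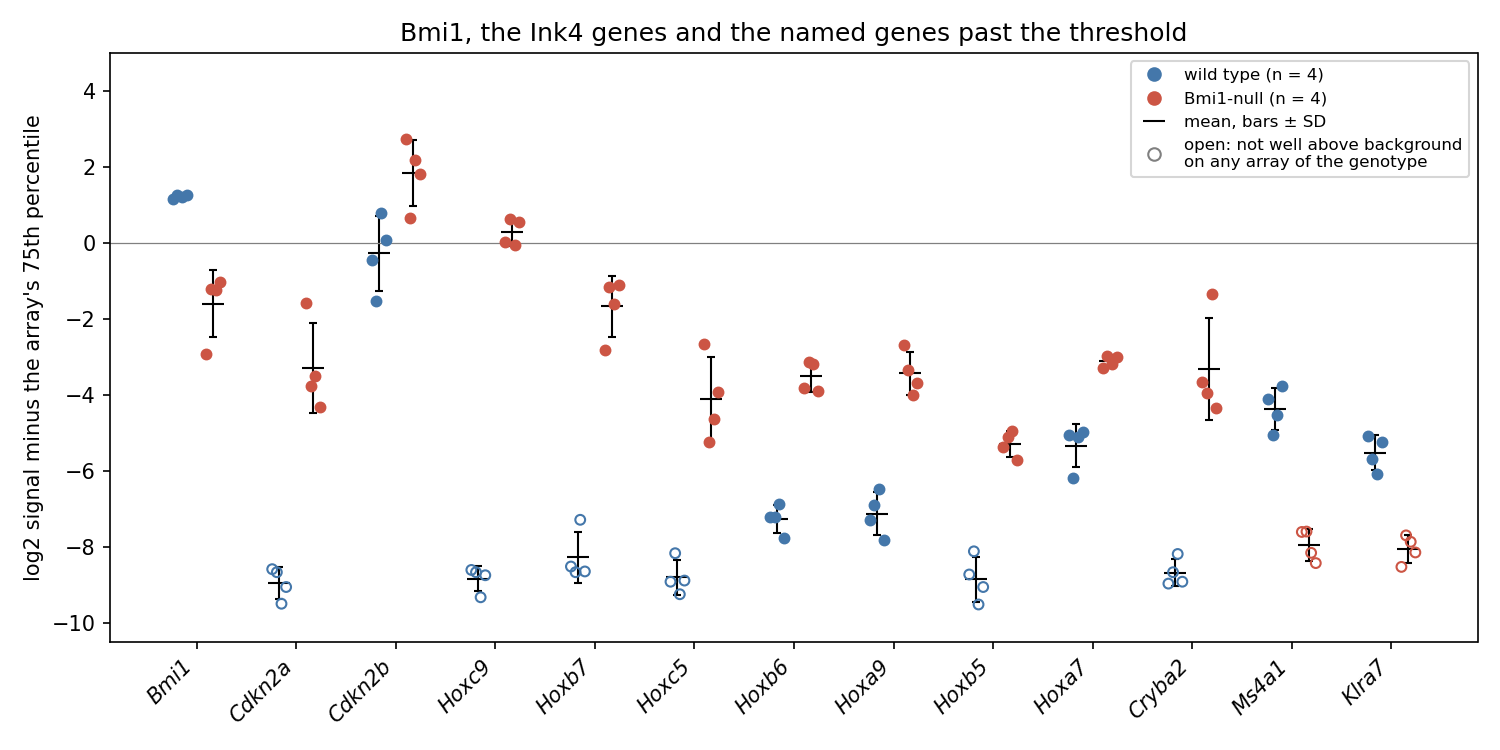
Each point is the log2 signal of a gene on an array minus that array's 75th percentile, for wild type (blue, n = 4) and Bmi1-null (red, n = 4), with mean and SD bars; open points mark a genotype with no array well above background. Cdkn2a and the Hox genes shown were higher on every Bmi1-null array than on any wild-type array, while Ms4a1 and Klra7 were lower, although the change of Klra7 reversed with normexp (0.38).

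Hox genes, which encode the homeobox factors that specify position along the body axis, made up most of the genes that rose. Of 39 Hox genes listed, 36 had a probe and 15 could be tested. Of these, 7 rose and 0 fell, or 8 and 0 adjusted over the list alone. Hoxc9 rose by at least 135.5-fold (limma adjusted p = 6.93e-07) and Hoxb7 by at least 35.04-fold (adjusted p = 8.07e-04), the highest of the bounds. Hoxc5 rose by at least 6.44-fold (adjusted p = 0.0150) and Hoxb5 by at least 2.85-fold (adjusted p = 0.00475). These 4 genes were well above background on every Bmi1-null array and on no wild-type array. Hoxb6 (log2 change 3.76, SE 0.27, adjusted p = 0.00108) and Hoxa9 (3.69, SE 0.36, adjusted p = 0.00655) were each well above background on 1 wild-type array. Hoxa7, measured on all arrays, rose from −5.33 ± 0.57 to −3.12 ± 0.15 (SD, n = 4 each; log2 change 2.22, SE 0.28, adjusted p = 0.0463).

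Other members of the clusters were measured in both genotypes without a call. Hoxa3, Hoxb3, Hoxd4 and Hoxd8 were well above background on all 8 arrays, with log2 changes of 0.34, −0.34, 1.1 and 0.13 (SE 0.26, 0.35, 0.61 and 0.35). A second Hoxb3 probe was not well above background on any array and was not tested. It was at −9.01 ± 0.29 in wild type and −6.72 ± 0.78 in Bmi1-null (SD, n = 4 each). No array had a signal well above background for 15 of the Hox genes, Hoxa10 and Hoxd13 among them. The list as a whole had a median log2 change of 2.22, or 1.40 with dim genes at their bound, and 1.12 with normexp and 0.70 in the authors' table (camera adjusted p = 2.09e-21). The filter left out Hox genes dim in both genotypes, while Hoxb5, Hoxb7, Hoxc5 and Hoxc9 met it on Bmi1-null arrays alone. These values therefore hold only for the 15 genes tested. The list passed in all 23 alternatives (adjusted p up to 0.0332 by camera or fry), among them the estimated correlation (adjusted p = 0.00149). With dim genes at their bound its median was 1.56 and 1.46 within the slides. Hoxc9 and Hoxb7 passed in all 20 alternatives in which they were tested (adjusted p up to 1.57e-04 and 0.0181). Their log2 changes there went down to 4.33 and 2.70, below the log2 bounds of 7.08 and 5.13 behind the folds above. The number of Hox genes that rose was only 2 with normexp, 4 in the authors' table and 4 with a common floor for dim probes. It was 0 when only probes measured on all 8 arrays were tested. Hoxb5, Hoxc5 and Hoxa9 lost their calls with normexp (adjusted p = 0.249, 0.206 and 0.159), in the authors' table (0.221, 0.629 and 0.0769) and with a common floor (0.769, 0.769 and 0.0579), where their log2 changes were 0.58, 1.76 and 2.44. Hoxb6 and Hoxa7 lost theirs with normexp, where their log2 changes were 1.52 and 1.27 (adjusted p = 0.249 and 0.185).

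Across the array, 12 of 22435 genes passed, 10 higher and 2 lower in Bmi1-null. With median scaling the split was 10 higher and 4 lower. At an unadjusted p under 0.05 there were 1385 genes, where chance gives 1122. Genotypes did not overlap in 692 genes (3.08%, where chance gives 2.86%). Of the 12, 9 were not well above background in a whole genotype. Besides Cdkn2a and the Hox genes, Cryba2, which encodes a beta-crystallin, rose by at least 11.1-fold (limma adjusted p = 0.0150), and 1 feature without a gene symbol rose by at least 26.6-fold (adjusted p = 2.71e-05). Igf2bp3, which encodes an RNA-binding protein of fetal tissues, had a log2 change of 1.84 (SE 0.27) and did not pass (adjusted p = 0.0787). It passed with normexp, in the authors' table and with array weights (adjusted p = 0.0381, 0.0487 and 0.0499), with adjusted p up to 0.284 in the other alternatives.

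Lower in Bmi1-null were Ms4a1, which encodes the B cell antigen CD20, by at least 3.36-fold (limma adjusted p = 0.00475), and Klra7, a Ly49 receptor of natural killer cells, by at least 1.52-fold (adjusted p = 0.0155). Klra7 belongs to a family of near-identical genes, and its probe may read several of them. Neither was well above background on any Bmi1-null array. The next genes by p did not pass. Among them were Fcmr (log2 change −1.72), a receptor for immunoglobulin M, and the lectin genes Mgl2 (−1.88) and Clec10a (−1.76), with adjusted p of 0.0631, 0.148 and 0.185. Ifng, which encodes interferon gamma, Fndc7, the lectin gene Clec4f and Odf3l1 were not well above background on any Bmi1-null array (adjusted p = 0.0631, 0.163, 0.185 and 0.158). The first 3 were at least 1.09-fold, 1.68-fold and 7.38-fold lower there, and for Odf3l1 no bound could be given. For Ifng none could be given on slide 2 or without Bmi1-null replicate 1. Clec4f was at least 16.8-fold lower within slide 1 and 3.25-fold within slide 2. Ms4a1 and Klra7 lost their calls with normexp (log2 change −0.18 and 0.38, the latter reversed), in the authors' table (−1.19 and −0.58) and with a common floor (−1.5 and −0.40). With normexp the log2 changes of Ifng, Fcmr, Odf3l1 and Fndc7 reversed to above 0, and none passed. With array weights Ifng, Fcmr, Mgl2 and Clec10a passed (adjusted p = 0.0499, 0.0486, 0.0499 and 0.0486). Ifng also passed without wild-type replicate 3 (0.0227), Fcmr without Bmi1-null replicate 2 (0.0311), Odf3l1 with sex as a covariate (0.0149) and Clec4f without wild-type replicate 2 (0.0294). Over all alternatives the adjusted p of these genes ran up to 0.831 for Ifng, 0.852 for Fcmr, 0.521 for Mgl2, 0.650 for Clec10a and 0.821 for Clec4f.

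With slide as a block 13 genes passed, 11 of the 12 among them; Hoxa7 did not (adjusted p = 0.0564). Within slide 1 and slide 2, Hoxc9 was at least 139-fold and 132-fold higher in Bmi1-null, Hoxb7 at least 28.3-fold and 43.4-fold, and Cdkn2a at least 17.4-fold and 7.37-fold. Ms4a1 was at least 4.92-fold and 2.30-fold lower, and Klra7 at least 2.12-fold and 1.09-fold lower. Some calls were lost with 1 array fewer. Hoxa7 lost its call in 14 of 21 alternatives, among them each array left out except wild-type replicate 2 (adjusted p up to 0.152), where its log2 change was 2.17 to 2.33. With normexp it was 1.27. Cryba2 lost its call without any 1 of the wild-type arrays (adjusted p = 0.0517 to 0.0753) and with sex as a covariate (0.0541). It also lost it with normexp (log2 change 1.93, adjusted p = 0.249), in the authors' table (2.05, adjusted p = 0.620) and with a common floor (2.55, adjusted p = 0.769). Hoxc5 lost it without wild-type replicate 1, 3 or 4 or Bmi1-null replicate 4 (adjusted p up to 0.0971), and Klra7 without wild-type replicate 1, 2 or 4 or Bmi1-null replicate 3 or 4 (up to 0.0971). With each array left out the bounds were at least 7.03-fold to 14.1-fold for Cryba2, the lowest without Bmi1-null replicate 3, 4.59-fold to 8.38-fold for Hoxc5 and 1.36-fold to 1.73-fold for Klra7. Without Bmi1-null replicate 1, 17 genes passed.

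Genes of epithelium and enamel were higher in Bmi1-null as groups, although no single member passed. All 16 tested keratin, adhesion and identity genes of dental and general epithelium had positive changes, or 15 with quantile normalisation (median 0.71, camera adjusted p = 5.13e-09; adjusted p = 0.199 with an estimated correlation). Krt14 and Krt5, keratins of basal epithelium, had log2 changes of 0.97 and 0.81 (SE 0.29 and 0.26), which went down to 0.38 and 0.22 over all alternatives. The median of the list was 0.49 and 0.76 within the slides, 0.45 without Bmi1-null replicate 1, 0.37 with quantile normalisation and 0.39 in the authors' table. Of 17 ameloblast and enamel genes, 16 had positive changes, or 13 with quantile normalisation and in the authors' table (median 0.67, camera adjusted p = 3.67e-06; adjusted p = 0.156 with an estimated correlation), and 2 rose adjusted over the list alone. These were Ambn (0.95, SE 0.22) and Amelx (0.94, SE 0.24), which encode the enamel matrix proteins ameloblastin and amelogenin. Over all alternatives their log2 changes went down to 0.36 and 0.22. The median of this list was 0.61 and 0.81 within the slides, 0.39 with quantile normalisation and 0.36 in the authors' table.

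Beside these groups, the mesenchyme list had a median of −0.10 (camera adjusted p = 0.680), with Col1a1 at 0.98 and Postn at −0.93. It passed as lower in Bmi1-null with normexp, with quantile normalisation and in the authors' table (adjusted p = 0.00347, 0.0430 and 0.0161). Genes of keratinised oral epithelium had a median of 0.52 (adjusted p = 0.00150; adjusted p = 0.251 with an estimated correlation; 0.47 and 0.43 within the slides, and 0.34 without Bmi1-null replicate 3), with Krt10 at 0.72 and Krt13 at 0.81. Markers of incisor epithelial progenitors had a median of 0.39 (adjusted p = 0.00888; adjusted p = 0.488 with an estimated correlation; 0.40 and 0.36 within the slides), with Fst at 0.95. Notch pathway genes had a median of 0.22 (adjusted p = 0.0354; adjusted p = 0.294 with an estimated correlation; 0.26 and 0.18 within the slides), with the receptor genes Notch2 at 0.96 and Notch1 at 0.92. Without Bmi1-null replicate 1 the progenitor and Notch medians were 0.18 and 0.09 and neither list passed (adjusted p = 0.398 and 0.234). Without Bmi1-null replicate 2 the Notch median was 0.40. Over all alternatives the progenitor list lost its call in 6 of 23 and the Notch list in 11 of 23, the latter also without wild-type replicate 1 or 2 or Bmi1-null replicate 4 (adjusted p = 0.0767, 0.119 and 0.140).

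**Figure D2:**
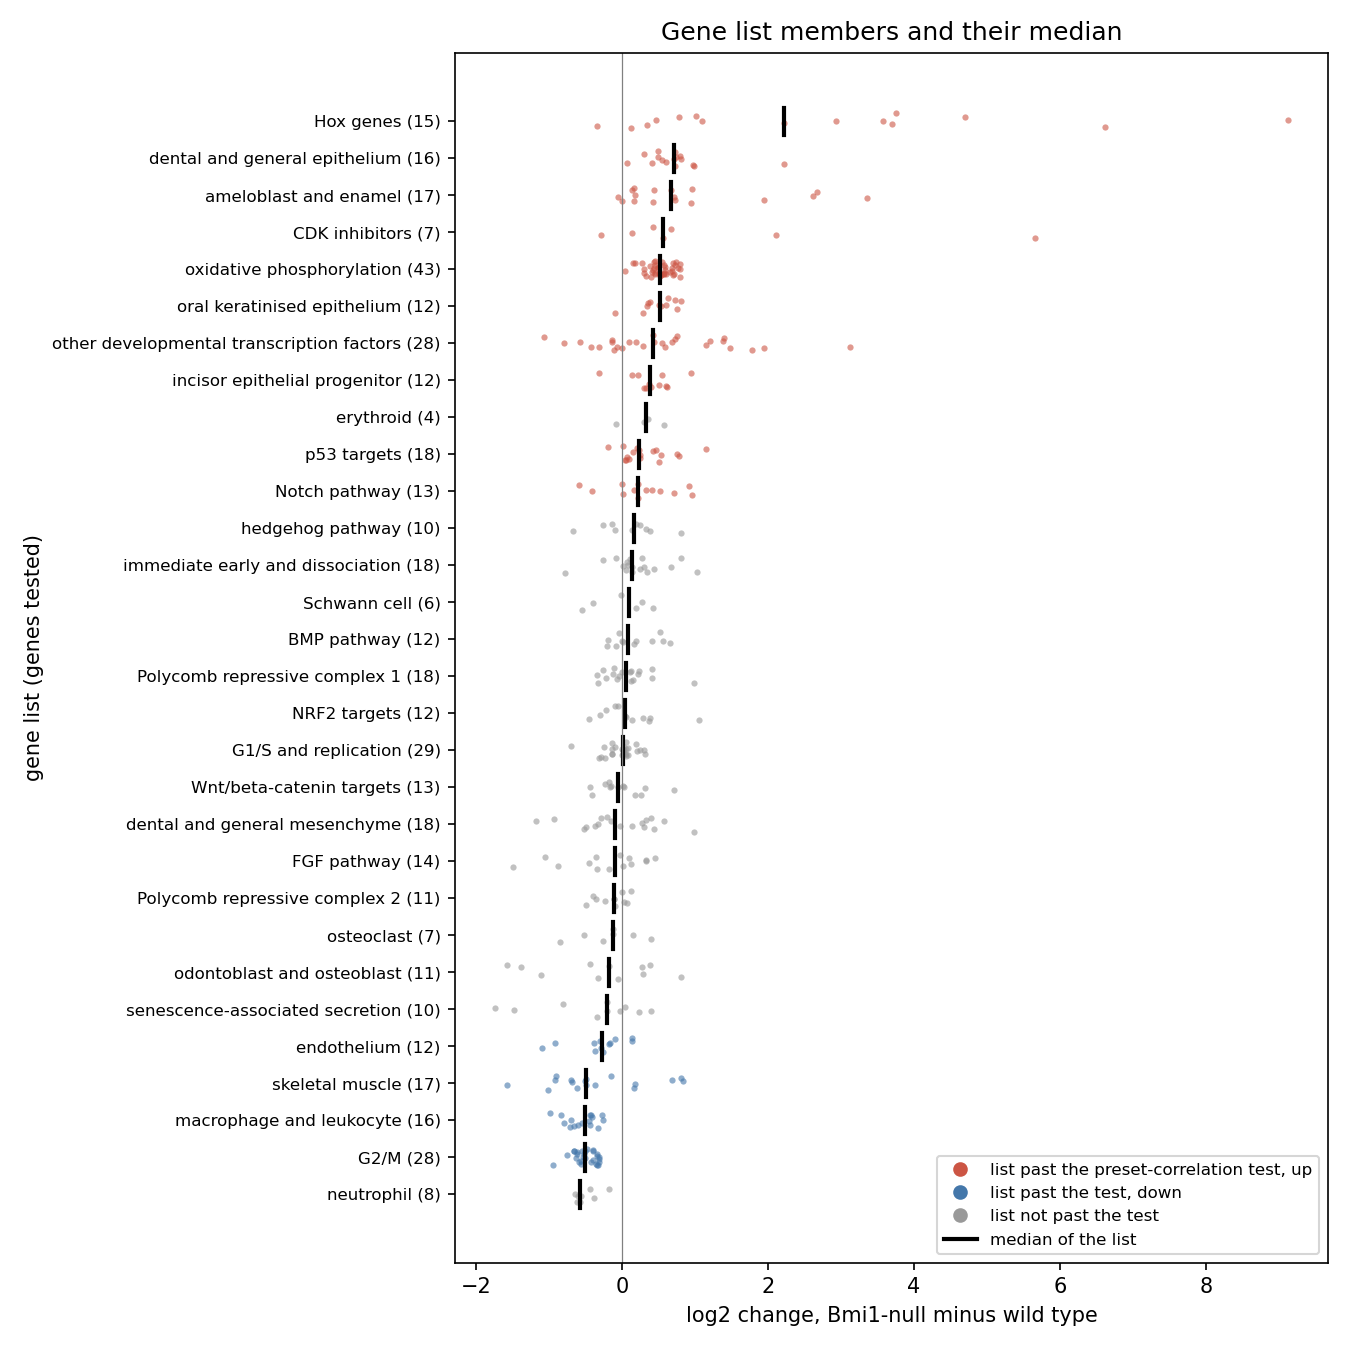
Each point is a gene's log2 change, Bmi1-null minus wild type, and each black line the median of its list, for the 30 lists tested; colour gives the camera test at the preset correlation. The Hox list had the highest median at 2.22, while the neutrophil list, which did not pass, had the lowest at −0.57. With normexp and in the authors' table the neutrophil median was −0.10 and −0.27, and no longer the lowest.

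Nuclear genes of the respiratory chain and ATP synthase were higher together: all 43 had positive changes, or 42 with quantile normalisation and in the authors' table, with a median of 0.52 (camera adjusted p = 9.24e-21; adjusted p = 0.171 with an estimated correlation). Uqcrq and Ndufa1 had log2 changes of 0.70 and 0.56 (SE 0.21 and 0.17), which went down to 0.285 and 0.154 over all alternatives. No member passed alone, and 23 had an unadjusted p under 0.05. The median was 0.45 and 0.64 within the slides, 0.23 with quantile normalisation and 0.25 in the authors' table. Of 18 targets of p53, 17 had positive changes, or 15 in the authors' table (median 0.24, camera adjusted p = 3.83e-04; adjusted p = 0.156 with an estimated correlation), and 1 rose adjusted over the list alone. That was Pmaip1, which encodes the pro-apoptotic protein Noxa (1.16, SE 0.22). Phlda3 was next at 0.78 (SE 0.26). The median was 0.18 and 0.29 within the slides, and the list did not pass with normexp (adjusted p = 0.139) or without a filter (0.0525). Developmental transcription factors outside the Hox clusters had a median of 0.43 over 28 genes, 18 of them above 0 (camera adjusted p = 3.83e-04; adjusted p = 0.171 with an estimated correlation). None passed over all genes, 5 rose adjusted over the list alone, and En2 and Evx1 had log2 changes of 1.94 and 3.12 (SE 0.35 and 0.62). Evx1 was well above background on 1 wild-type array, and with a common floor its log2 change was 1.38 (adjusted p = 0.769). The median was 0.39 and 0.28 within the slides, and 0.21, 0.25 and 0.19 without wild-type replicate 1, wild-type replicate 4 and Bmi1-null replicate 3. It was 0.71 with normexp and 0.15 in the authors' table.

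Genes of G2 and mitosis were lower together in Bmi1-null. All 28 had negative changes, or 26 with normexp, with a median of −0.50 (camera adjusted p = 5.13e-09; adjusted p = 0.471 with an estimated correlation). Ttk, a spindle checkpoint kinase, and Kif11, a mitotic kinesin, were at −0.94 and −0.66 (SE 0.31 and 0.28), and no member passed; Ttk was at 0.07 with normexp. The median was −0.30 and −0.72 within the slides, and −0.26 without wild-type replicate 2. By array, the mean of these genes was 0.90 ± 0.61 (SD, n = 4) in wild type and 0.40 ± 0.18 (n = 4) in Bmi1-null, a difference no larger than this spread (exact permutation p = 0.229). The mean was 1.27 and 1.56 on wild-type replicates 1 and 2, both male, but 0.44 and 0.34 on replicates 3 and 4, both female, within the 0.24 to 0.64 of the Bmi1-null arrays. Genes of the G1/S transition and replication had a median of 0.01 and a mean of −0.02 (camera adjusted p = 0.682), with Ccne2 at −0.70 and Rfc3 at −0.29. It passed as lower in Bmi1-null with normexp (median −0.03, adjusted p = 0.00310), with sex as a covariate (−0.15, adjusted p = 0.0147), and without wild-type replicate 3 (−0.15, adjusted p = 0.0279) or 4 (−0.13, adjusted p = 0.0202).

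Markers of leukocytes and vessels were also lower. All 16 tested macrophage and leukocyte genes had negative changes, or 15 with normexp (median −0.50, camera adjusted p = 2.45e-07; adjusted p = 0.250 with an estimated correlation), with the leukocyte antigen gene Ptprc at −0.84 and H2-Aa at −0.71 (SE 0.34 and 0.30). Within the slides the median was −0.78 and −0.31. The neutrophil list had a median of −0.57 over 8 genes (camera adjusted p = 0.143), with Camp at −0.65 and Ngp at −0.58 (0.24 with normexp), but −2.16 and 1.11 within the slides. It passed with sex as a covariate (−0.82, adjusted p = 0.0381), without wild-type replicate 3 (−0.91, adjusted p = 0.00335) and without Bmi1-null replicate 3 (−1.11, adjusted p = 6.21e-04), while without Bmi1-null replicate 1 the median was 0.15 (adjusted p = 0.824) and without wild-type replicate 4 it was −0.23. Endothelial genes had a median of −0.28 (adjusted p = 0.00557; adjusted p = 0.471 with an estimated correlation; −0.48 and −0.03 within the slides), with Tek at −1.10 and Vwf at −0.92. This list did not pass without wild-type replicate 4 or Bmi1-null replicate 4 (adjusted p = 0.0921 and 0.0887), and its median without the former was −0.16. Skeletal muscle genes had a median of −0.49 (adjusted p = 0.0354; adjusted p = 0.550 with an estimated correlation), with Actn3 at −0.92 and Ckm at −1.58 (0.37 with normexp). Its median was −1.36 and 0.15 within the slides, so the shift was not seen on both, and 5 of the 8 arrays each removed its call when left out (adjusted p up to 0.435). It also lost its call with normexp (median −0.18, adjusted p = 0.119), quantile normalisation (adjusted p = 0.133), the authors' table (0.109) and the mean of probes (0.0583). The median was −0.24, −0.74 and −0.32 without wild-type replicate 1, 2 and 4.

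**Figure D3:**
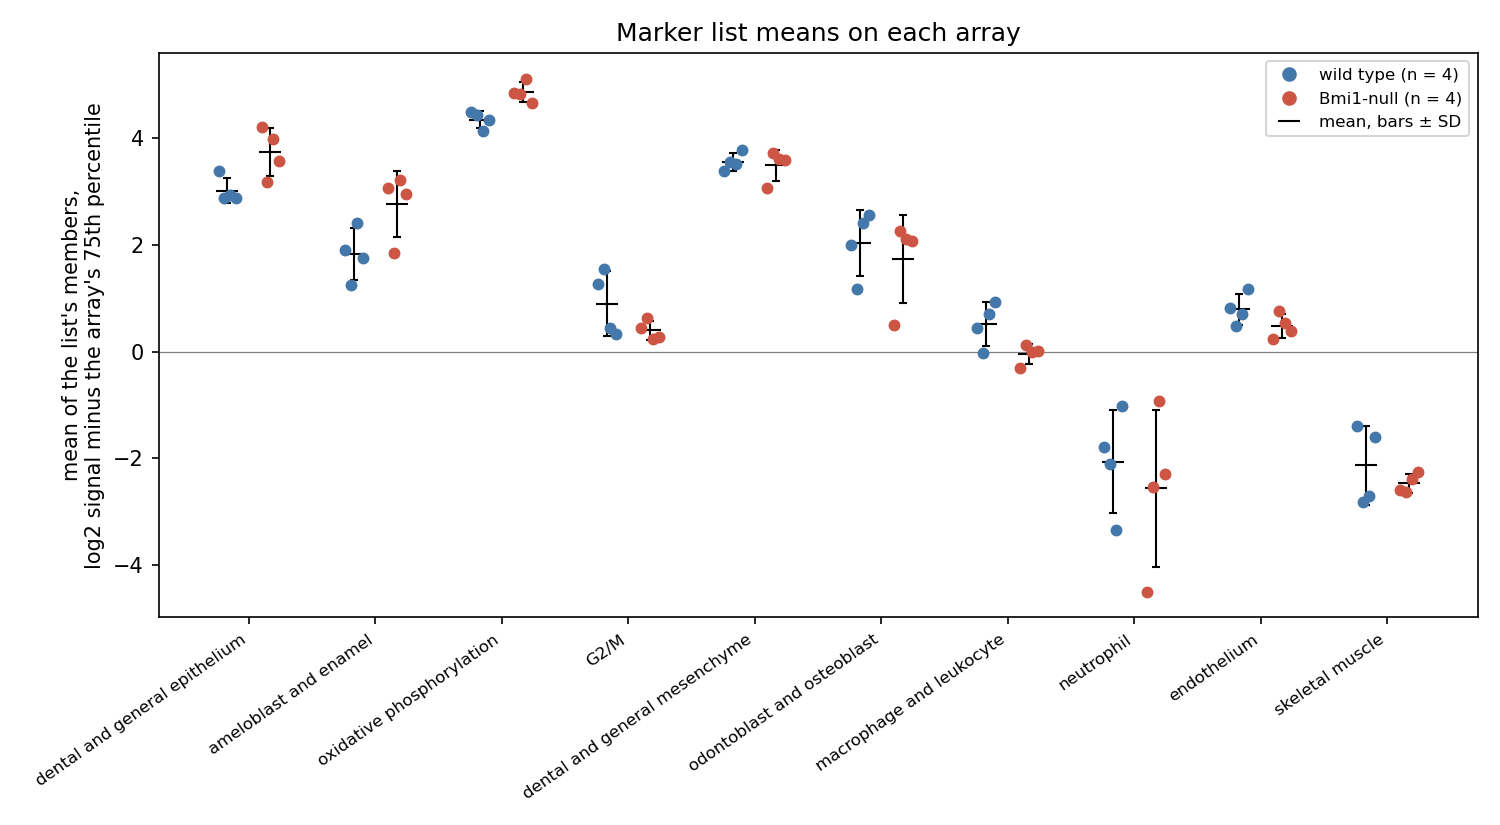
Each point is the mean over a list's genes of log2 signal minus the array's 75th percentile, on each of the 4 wild-type (blue) and 4 Bmi1-null (red) arrays, with mean and SD bars. Respiratory chain genes were higher on every Bmi1-null array (4.87 ± 0.19) than on any wild-type array (4.35 ± 0.16), while neutrophil genes ranged widely within both genotypes.

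The remaining lists did not pass with all arrays and the settings used throughout. Subunits of Polycomb repressive complex 1 other than Bmi1 had a median of 0.05 (camera adjusted p = 0.769), with Yaf2 at −0.33. Polycomb repressive complex 2 had −0.12 (adjusted p = 0.197), with Eed at −0.50 and Ezh2 at −0.36. The FGF list had −0.10 (adjusted p = 0.143), although Fgf3, at −1.50 (SE 0.37), fell adjusted over the list alone. The change of Fgf3 was −0.80 and −2.20 within the slides, and as small as −0.284 over all alternatives. Fgf10 was at −0.87. Median changes were 0.17 for hedgehog genes (adjusted p = 0.682; Gas1 −0.67), −0.06 for Wnt targets (0.769; Lef1 0.71, Nkd2 −0.41) and 0.09 for BMP genes (0.419; Id3 0.56, Bmp7 0.53). They were −0.18 for odontoblasts and osteoblasts (adjusted p = 0.340; Spp1 −1.39, Ibsp −1.10), −0.13 for osteoclasts (0.396; Atp6v0d2 −0.85, or 0.52 with normexp, Ctsk −0.53), 0.32 for erythroid cells (0.419; Slc4a1 0.58, Alas2 0.35) and 0.09, with a mean of −0.01, for Schwann cells (0.769; Gfra3 0.42). Immediate early genes had 0.14 (adjusted p = 0.119; Hspa1a 0.80, Egr2 −0.78), NRF2 targets 0.05 (0.518; Srxn1 0.39, Prdx1 0.37) and genes of the senescence-associated secretion −0.20 (0.122; Mmp13 −1.74). With normexp, where the median of all genes was 0.179, the osteoclast median was 0.38, with 5 of 7 genes above 0. The median of the secretion list was then 0.08, with 6 of 10 genes above 0. Without Bmi1-null replicate 1 the log2 change was −0.70 for Mmp13 and −0.75 for Spp1. Of the 72 genes that the naming rule took and that are reported, 18 had a change more than 1.5 times smaller without that array, none of them past the threshold. Some of these lists passed in an alternative, in the same direction. The FGF list did with no filter, with array weights and without Bmi1-null replicate 1 (adjusted p = 0.0274, 0.0231 and 0.00798), and Polycomb repressive complex 2 with normexp and with no filter (0.00782 and 0.0499). The secretion list passed with no filter, with sex as a covariate and without wild-type replicate 3 (adjusted p = 0.0274, 0.0399 and 0.0439). Odontoblasts and osteoblasts passed with normexp and without wild-type replicate 2 (0.0156 and 0.0382), osteoclasts without wild-type replicate 2 (0.0436), and immediate early genes without Bmi1-null replicate 2 (median 0.37, adjusted p = 0.00322).

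In all, 14 of 30 lists passed at the preset correlation, 10 up and 4 down, and the same 14 passed with slide as a block. With a correlation estimated from the data only the Hox list passed. With fry, 4 passed: Hox genes, inhibitors of cyclin-dependent kinases, p53 targets and the respiratory chain. The means by array of those 4 lists and of the Notch list did not overlap between genotypes (exact permutation p = 0.0286, the smallest possible, and 0.177 after Benjamini-Hochberg adjustment over 31 lists). For the epithelium, ameloblast and leukocyte lists the exact permutation p was 0.0571, 0.0857 and 0.114 (n = 4 and 4), or 0.253, 0.295 and 0.354 adjusted.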

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

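Of the tests in this part, those of sex, of Bmi1-null replicate 1 alone, of a smaller share of other cell types, of outlying spots and of a common floor were chosen after the results were seen. In 193 groups of 4 arrays, 11 held a value far from the other arrays of its genotype, where chance gives about 9.7, or about 1 group in every 20.

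Several of them concerned Bmi1-null replicate 1. Bmi1 was −2.92 on that array against −1.23 to −1.04 on the others, a gap of 0.902 of the group's range. Mmp13, a collagenase gene of bone and dental mesenchyme, was −0.22 against 3.68 to 4.26 (0.872). The mean of the odontoblast and osteoblast genes was 0.51 against 2.07 to 2.26 (0.895), and that of the hedgehog genes 0.70 against 0.06 on each other array (0.989). It also had 75 outlying spots against 3 to 9 (0.917). The other Bmi1-null groups were Krt10 in replicate 2, at −4.73 against −3.71 to −3.52 (0.847), and the osteoclast mean in replicate 3, at −2.11 against −2.70 to −2.61 (0.844).

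In wild type, Hoxa7 was −6.19 in replicate 2 against −5.11 to −4.99 (0.901), and Hspa1a was 0.90 in the same replicate against 1.82 to 1.98 (0.848). The epithelium mean was 3.38 in replicate 1 against 2.89 to 2.93 (0.914). The Schwann cell mean was −0.54 in replicate 3 against −0.18 to −0.12 (0.859).

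The first pattern weighed is that Bmi1-null replicate 1 stands apart. The outlying spots cannot account for it, since they were left out and its mean correlation with the other Bmi1-null arrays was still 0.951, below every other array. A different mix of cell types may contribute: against the mean of replicates 2 to 4, its neutrophil genes had a median deviation of −2.63, its odontoblast genes −1.36 and its mesenchyme genes −0.66, while epithelium genes were at 0.57, each outside 99% of random lists matched on mean signal. The test of a shift common to female samples was undecided. The correlation of replicate 1 with female wild-type arrays exceeded that with male ones by 3e-04 (0.9472 against 0.9469). Its correlations with the male arrays were themselves 0.9592 and 0.9346, so this difference decides nothing. On the main axis the female wild-type arrays scored −24.77 and −16.32, between the male wild-type arrays at −50.02 and 6.16. They did not stand out towards replicate 1, but with so few arrays such a shift is not excluded. An effect of sex within Bmi1-null also stays open. Replicate 1 was the only female Bmi1-null sample, so sex cannot be told apart there from its other differences. The number in its sample title was also far below those of all other samples. What that number stands for is not given in the sources used here, and whether this sample was collected apart was not tested.

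For the lower leukocyte transcripts in Bmi1-null, weighed next, the dimmer Bmi1-null arrays do not account for the macrophage list: its median of −0.50 lay at percentile 0 of 10000 random lists matched on mean signal. For Ms4a1 and Klra7, not measured above background in Bmi1-null, the dim floor stays open. A common floor left log2 changes of −1.5 (SE 0.26) and −0.40 (SE 0.19), against bounds of at least 3.36-fold and 1.52-fold lower. With normexp they were −0.18 (SE 0.25) and 0.38 (SE 0.30). Those normexp values cannot decide it, because the offset of 50 lifts dim probes more on arrays with a lower 75th percentile. With sex as a covariate the median of the macrophage list was −0.47. A smaller share of leukocytes in these samples may contribute but was left undecided: of 22 markers of B, T and NK cells written down before their values were seen, 63.6% had changes below 0 (B cell median −0.41, or −0.07 without Bmi1-null replicate 1; T and NK cell median −0.07, or −0.24 without wild-type replicate 3 or Bmi1-null replicate 3), fewer than a loss of these cells was predicted to give. Mast cell markers, which that prediction did not cover, were below 0 in 6 of 6 (median −0.95), or 5 of 6 without Bmi1-null replicate 1 (median −0.58). An effect of the genotype on the leukocyte transcripts also stays open.

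Higher epithelial and respiratory chain transcripts in Bmi1-null were the third pattern. A trend with brightness is argued against as the whole source only. The medians of the epithelium, ameloblast and respiratory chain lists all lay at percentile 100 of the matched random lists. Most of those random lists had medians of 0.03 to 0.29, −0.03 to 0.23 and 0.12 to 0.28, in the same order. Equally bright genes thus tended to rise too, and such a trend may account for part of the shifts. With quantile normalisation the medians of the epithelium, ameloblast and respiratory chain lists were 0.37, 0.39 and 0.23. Bmi1-null replicate 1 alone is not the source: without it the lists kept at least 0.63 of their medians (0.45, 0.53 and 0.56 against 0.71, 0.67 and 0.52). A smaller share of all other cell types could not be excluded: it would lower macrophage and mesenchyme genes alike, and the difference between their means changed by −0.50 (exact permutation p = 0.0857, n = 4 and 4). An effect of the genotype on the epithelium also stays open.

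The 8 arrays can be split into 4 and 4 in 35 ways. For genes, 2 of the 35 splits gave at least the 12 of the real split, so chance cannot be excluded by this count. The other one was the split by slide, which called 314 genes, several times the real count and a sign of a difference between the slides. Whether that difference lay in the slides or in the samples on them was not tested. Every remaining split called at most 1. Of these 314 genes 313 were higher on slide 2, 0 were among the 12, and with slide as a block the genotypes still differed in 13 genes. The 18 splits with 2 arrays of each slide on both sides are too few for a share under 0.05; the real one gave 12 genes and the highest of the others 1. For lists, 3 of the 35 splits gave at least the 14 of the real one, with 16 as the highest of the others, so chance cannot be excluded for the number of lists called at the preset correlation.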

How the results depend on the processing

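The number of genes that differed was within 1.5 times the 12 reported under quantile normalisation, median scaling, no filter, the mean of probes, trended variances, slide as a block, sex as a covariate and outlying spots kept (11 to 14). It was 5 with normexp, 7 in the authors' table, 0 with a filter on all 8 arrays, 26 with array weights and 6 with a common floor, an alternative chosen after seeing the data. Leaving out each array in turn gave 8 to 17. The count of Hox genes that rose, 7, became 2 with normexp, 4 in the authors' table, 0 with the filter on all arrays and 4 with the common floor, and was 5 to 7 with an array left out. The strict filter removes by construction every gene that is dim in a genotype; 1233 genes there had an unadjusted p under 0.05 in limma. For the other settings the cause was not tested. By construction, though, normexp added its offset of 50 before the 75th percentile was subtracted. This lifts dim probes more on arrays with a lower 75th percentile. The Bmi1-null arrays had the lower mean (603 against 1177 in processed signal). How far this accounts for the changes with normexp was not tested. Klra7 reversed with normexp (0.38, adjusted p = 0.523), over a range of adjusted p up to 0.821. Not passing on either side, Ifng (0.50), Fcmr (0.11), Odf3l1 (0.60), Fndc7 (0.32), Ttk (0.069), Atp6v0d2 (0.52), Ngp (0.24) and Ckm (0.37) also reversed with normexp, and Camp without Bmi1-null replicate 1 (range with an array left out −1.21 to 0.021). The median of all genes shifted to 0.179 with normexp and 0.126 with no filter, and values there are relative to that. With normexp 4324 genes had an unadjusted p under 0.05 in limma, against 1385 with the settings used throughout. The change with normexp was therefore not limited to the genes that reversed. The number of lists, 14, was 1 with an estimated correlation, 4 with fry, 12 to 17 under the other settings and 11 to 17 with an array left out. Over the genes that the naming rule took and the settings, 1556 values kept their side and direction, 50 were weaker, 19 stronger and 10 reversed; over lists, 586 were the same, 50 weaker, 22 stronger and 32 reversed. The direction of camera reversed only in lists that passed on neither side. With normexp these were Polycomb repressive complex 1, hedgehog, BMP, Schwann cell and NRF2 (adjusted p = 0.289, 0.559, 0.330, 0.588 and 0.386), in the authors' table BMP and Schwann cell (0.882 and 0.921), and with no filter Polycomb repressive complex 1, hedgehog, BMP, Schwann cell and NRF2 (0.230, 0.629, 0.832, 0.230 and 0.714). The Schwann cell list also reversed with the filter on all arrays (0.901), the mean of probes (0.623) and sex as a covariate (0.867), hedgehog with the mean of probes (0.860), and Polycomb repressive complex 1, G1/S and hedgehog with array weights (0.540, 0.540 and 0.622). With an array left out, lists that reversed at least once had adjusted p of 0.324 to 0.994 (Polycomb repressive complex 1), 0.0202 to 0.907 (G1/S), 0.324 to 0.981 (hedgehog), 0.606 to 0.854 (Wnt), 0.372 to 0.966 (mesenchyme), 0.0382 to 0.960 (odontoblast), 6.21e-04 to 0.824 (neutrophil) and 0.488 to 0.970 (Schwann cell). No paired analysis was possible because the labels give the genotypes no shared replicate numbers. Signal over background limits 9 of the 12 genes, which were not measured in a whole genotype, so their folds are bounds.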

Other observations

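The test of Hox paralog groups and the common floor were chosen after the results were seen. The stefin genes Stfa1, Cstdc5 and Csta1, which encode small inhibitors of cysteine proteases, were higher on every Bmi1-null array than on any wild-type array. They were chosen after their values were seen. Stfa2, another stefin gene, did not separate the genotypes in this way. It was at −7.76 on Bmi1-null replicate 1, below its wild-type mean of −6.35, with a mean of −4.21 over Bmi1-null replicates 2 to 4. Stfa1 was not well above background on any wild-type array and was at least 11.9-fold higher in Bmi1-null, or 4.38-fold and 32.4-fold within the slides. Cstdc5, well above background on 2 wild-type arrays, and Csta1, measured on all arrays, had log2 changes of 4.14 and 3.54 (SE 0.67 and 0.71), with 2.05 and 5.03 for Csta1 within the slides. Among the Bmi1-null arrays Stfa1 and the mean of the neutrophil list were both lowest on replicate 1 (−5.49 and −4.5) and highest on replicate 3 (−1.51 and −0.92). This did not extend to wild type, where the neutrophil mean was −3.34 to −1.01 while Stfa1 was −8.23 to −7.48. The difference in Stfa1 between genotypes therefore did not follow the neutrophil list. None of the 3 passed with all arrays weighted alike (limma adjusted p = 0.158, 0.156 and 0.297). All 3 passed with array weights (adjusted p = 0.0119, 0.0150 and 0.0499), and Cstdc5 with slide as a block (0.0420). Without Bmi1-null replicate 1, an alternative fixed beforehand, all 3 passed (adjusted p = 0.0107, 0.0158 and 0.0463), Stfa1 at least 20.1-fold higher and the others with log2 changes of 4.77 and 4.21. With a common floor the log2 changes were 2.65, 3.28 and 3.49. Over the 4 alternatives computed for them the adjusted p ran from 0.0107 to 0.769 for Stfa1, 0.0150 to 0.725 for Cstdc5 and 0.0463 to 0.725 for Csta1. These genes are near-identical copies in a cluster, so their probes are not independent. Csf3r, the receptor of granulocyte colony-stimulating factor, also passed there (adjusted p = 0.0107), where no Bmi1-null array left was well above background and it was at least 1.35-fold lower. It passed with array weights (adjusted p = 0.0486), but not with all arrays weighted alike (adjusted p = 0.689), with slide as a block (0.622) or with a common floor (log2 change −0.31, adjusted p = 0.769).

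Mast cell markers, from a list written down before its values were seen, all had negative changes: 6 of 6 tested, with a median of −0.95 at percentile 0 of random lists matched on mean signal. Without Bmi1-null replicate 1, on which Mcpt4 and Cma1 were lowest, 5 of 6 were below 0 and the median was −0.58, and without Bmi1-null replicate 2 it was −1.43. Mcpt4 and Cma1, proteases of mast cell granules, had log2 changes of −1.73 and −1.19 (SE 0.65 and 0.55), or −1.11 and −0.74 without Bmi1-null replicate 1. By array the mean of the list changed by −1.02 (exact permutation p = 0.0857, n = 4 and 4). The B cell list changed by −0.25 (exact permutation p = 0.0857) and the T and NK cell list by −0.40 (exact permutation p = 0.143). Their medians lay at percentiles 1.27 and 39.07 of the matched random lists. Changes were below 0 in 5 of 9 tested B cell markers and 9 of 13 tested T and NK cell markers. Pou2af1, at −0.86, and Cd3d, at −1.16, had the smallest p of their lists. Cr2, a B cell marker, and Cd3e, a T cell marker, went the other way, at 0.77 and 0.32.

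Of the genes that separated the slides 29.3% had a symbol, and among those chosen after their values were seen Vmn1r237, a pheromone receptor gene, was at −7.34 on slide 1 and −1.09 on slide 2, Olfr1359, an odorant receptor gene, at −5.67 and −1.27, and the testis gene Pgk2 at −7.08 and −0.67. On Bmi1-null replicate 1, likewise chosen after the values were seen, Dnajb8 was −7.97 against a mean of 0.68 over replicates 2 to 4, Syt6 −6.57 against 1.70, Kcnq1ot1 −6.98 against 0.30 and Slc4a7 −4.11 against 3.04.

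The 7 Hox genes that rose belong to paralog groups 5 to 9, the central part of a Hox cluster. They were 7 of the 14 Hox genes of these groups with a probe, and none was in the Hoxd cluster. Hoxd8, in these groups and measured on all arrays, had a log2 change of 0.13. A 2-sided Fisher's exact test of these groups against the others (p = 4.11e-04) decides nothing, because the groups were read off the genes that rose and genes too dim to be tested counted as not risen. Hoxb2 and Hoxc13, outside those groups, were well above background on 2 and 3 Bmi1-null arrays and on no wild-type array. Hoxc13 was the 8th Hox gene to rise adjusted over the list alone, and it passed over all genes without Bmi1-null replicate 2 (adjusted p = 0.0236), against 0.142 to 0.821 in the other alternatives that tested it. Hoxb2 passed when dim probes were not filtered out (adjusted p = 0.0433), the only setting that tested it.

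Spag6, a neighbour of Bmi1 chosen after its values were seen, was well above background on 4 Bmi1-null arrays and 1 wild-type array, with a log2 change of 1.94 (SE 0.28, limma adjusted p = 0.0787; 0.0181 with a common floor, where the log2 change was 1.16, and 0.0820 to 0.133 in the other alternatives computed for it). Commd3, on the other side of Bmi1, had a log2 change of 0.14 (SE 0.20). The hypothesis that a chromosome segment carried along with the targeted allele alters many neighbours was tested on the 40 tested genes nearest to Bmi1. Of these 2 (5%) had an unadjusted p under 0.05, against 67 of 1088 (6.16%) on the rest of the chromosome (1-sided Fisher's exact test p = 0.717). This argues against a broad effect of such a segment; an effect on Spag6 alone, through the altered allele itself, was not tested.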
